A study of Homo sapiens with 14 samples.

How the data were processed

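RNA from subcutaneous xenografts of U87-EV cells, an established human glioblastoma line, was measured on Affymetrix Mouse430_2 arrays, which carry mouse probes, so that the values describe the mouse stroma of each tumour. The hosts were female BALB/c SCID mice. There were 5 control arrays (saline), 5 dibenzazepine arrays and 4 bevacizumab arrays, 1 array per tumour. Per the labels each group held 5 mice, and the fifth bevacizumab tumour is not in the data used here. The labels give Homo sapiens as the organism, after the grafted cells. RNA of the human tumour cells can bind mouse probes, and this was not separated here.

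The deposited values are log2 expression values for 45101 probe sets on 14 arrays, background-corrected, normalised and summarised by the authors with GCRMA, as their processing notes name it. The notes also name GCOS 1.1.1.052 and R 2.11 without stating their roles, and no genome build is given. The values ran from 0.56 to 16.0, with medians per array between 3.14 and 3.29. They were analysed as deposited. For arrays there is no count depth, so the number of arrays limits the precision.

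Probe sets were joined to gene symbols with the platform annotation. Of the probe sets, 34945 carried 1 symbol, 932 carried several, 9160 had no gene name here and 64 were array controls. For each gene the probe set with the highest mean over the 14 arrays stood for the gene, and it was kept when it was above log2 4 on at least 4 arrays. This left 8940 genes of 18193. Probe sets with several symbols or none were tested apart. The annotation used here gives no chromosome positions, so genes are identified by symbol and, for the leading ones, by probe set.

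Differences were fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group over all 14 arrays and moderated two-sided tests. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Changes are given as log2 fold change ± SE. Adjusted p values beside single genes are from limma, and unless stated otherwise every treated array lay on the stated side of the mean of the other group. The 3 comparisons were dibenzazepine against control, bevacizumab against control, and dibenzazepine against bevacizumab. The last is the test of a difference between the effects of the treatments, since the controls cancel. The first 2 share the 5 control arrays, so their overlap was set beside 100 simulated draws of unchanged groups against the same controls, the overlap of independent lists, and the 20 ways of splitting the controls between them.

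There were 29 fixed gene lists: Notch targets, Notch pathway components, pan-endothelial, tip cell and VEGF-dependent endothelial genes, other vascular and matrix genes, markers of immune cells and of surrounding tissue, and response programmes. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists of a comparison. Beside it stand camera with an estimated correlation, fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, and a two-sided exact permutation test of the mean of the list per array, whose smallest p was 0.00794. Members called are counted over all genes tested and, where stated, adjusted over the list alone. The same kind of exact test compared array quality between groups.

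The genes named are, for each treatment against control, the 10 largest rises and 10 largest falls among called genes with every treated array on the same side of the control mean, the 4 members of each list with the smallest p, and a fixed set: Hes1, Hey1, Hey2, Heyl, Nrarp, Dll4, Notch3, Vegfa, Kdr, Flt1, Esm1, Apln, Angpt2, Pecam1 and Cdh5. For dibenzazepine against bevacizumab the rule took the 5 largest rises and falls and the fixed set. Genes outside the rule are named as chosen after their values were seen. The groups, tests, gene lists, rule for named genes and most alternatives were set before the data were examined.

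On data simulated from the same spread, with changes of log2 0.5, 1 and 2 added to known genes, the fit recovered 53.7%, 88.1% and 95.5% of them for dibenzazepine against control with 12 false calls, and 58.2%, 86.6% and 97.0% for bevacizumab against control with 8. With no change added it called 0 of 8940 genes in each comparison. On the simulated data with changes added, the list test called the 1 shifted list and 0 others. Genes were drawn independently there, whereas real lists were correlated (estimated at 0.92 for skeletal muscle). The simulation therefore does not show how often the list test makes false calls on the real data.

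The alternatives were other filters, normalisations, choices of probe set, fits, weights, thresholds, a replicate block, a skeletal muscle covariate and leaving out each array in turn. Leaving out controls 2 and 3, leaving out bevacizumab arrays 1 and 2, and list tests with each array centred on its median were added after seeing the data. No scan dates or batches are given in the sources used here.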

Results

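Gene expression was measured in the mouse stroma of U87-EV xenografts, tumours of an established human glioblastoma line grown under the skin of SCID mice, which lack mature T and B cells. Tumours of 0.35 to 0.45 cm3 received saline (5 arrays), dibenzazepine (5 arrays) or bevacizumab (4 arrays), with a second dose after 3 days and collection 4 h later. Dibenzazepine inhibits gamma-secretase, the enzyme that releases the active part of Notch receptors, and was given at 8.1 mmol/kg as the labels state it, a very large dose in that unit, so that the unit is in doubt. Bevacizumab, an antibody against VEGF-A, was given at 10 mg/kg. The probes are for mouse Vegfa, so VEGF-A made by the human tumour cells was not measured separately. The series title sets the question as how anti-VEGF and anti-Notch therapy regulate gene expression in living tumours.

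Over all probe sets, correlations between 2 arrays lay between 0.978 and 0.996. Over the genes tested, the mean correlation of an array with the others of its group was lowest for control replicate 4 (0.956), and lay between 0.972 and 0.988 for the other 13 arrays. Of 12 comparisons of array measures between groups, the difference between the 3' and 5' probe sets of Actb, a sign of RNA integrity, was 1.03 ± 0.06 (SD, n = 4) with bevacizumab and 1.13 ± 0.06 (SD, n = 5) in controls (exact p = 0.0397, adjusted p = 0.238). The share of probe sets above log2 4 was 33.7% with dibenzazepine and 34.1% with bevacizumab (exact p = 0.0318, adjusted p = 0.238). With exact p values no smaller than 0.00794, a single measure could not pass adjustment over the 12, so equal quality is not shown. The first principal component held 28.9% of the variance and separated the 4 bevacizumab arrays (19.3 to 32.1) from the other 10 (-18.2 to -1.90). Some tumours carried signals that their group did not. Skeletal muscle genes averaged 9.74 and 10.4 (log2) on control replicates 2 and 3. The other 3 controls had 4.04 to 6.42 and the treated arrays 3.90 to 6.32. Interferon response genes averaged 8.42 on control replicate 4, against 5.85 to 6.17 on the other controls.

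Dibenzazepine against control asks what blocking gamma-secretase does to the stroma. Blood vessel genes rose. The mean of 36 pan-endothelial markers went from 7.44 ± 0.04 (SD, n = 5) to 7.90 ± 0.12 (SD, n = 5), and all 5 treated arrays lay above every control (exact p = 0.00794). Cd93, an endothelial surface receptor (probe set 1456046_at), rose from 9.98 ± 0.14 to 11.02 ± 0.17 (SD, n = 5 each), and Cdh5, the adhesion molecule VE-cadherin (1433956_at), from 7.18 ± 0.21 to 8.01 ± 0.25. The pericyte gene Rgs5 (1417466_at) fell from 9.74 ± 0.50 to 7.86 ± 0.75, and the lymphatic growth factor gene Vegfc (1439766_x_at) from 7.34 ± 0.37 to 6.09 ± 0.10, a change of -1.25 ± 0.14 (SE) that was smaller with probe sets unique to 1 transcript (-0.45).

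Among the 36 pan-endothelial markers, 17 rose and 2 fell over all genes tested, and 26 rose and 2 fell when adjusted over the list alone. Their median change was 0.59 (camera adjusted p = 5.3e-20, and adjusted p = 0.0129 with an estimated correlation). Cd93 changed by 1.04 ± 0.09 (SE, adjusted p = 3.7e-05), the tight junction gene Cldn5 by 1.30 ± 0.23 (0.0105) and Cd34 by 0.89 ± 0.14 (0.00377). Pecam1 rose by 0.82 ± 0.14 (0.0071) and Kdr, the main VEGF receptor, by 0.62 ± 0.12 (0.0166). The 2 markers that fell, chosen for naming after their values were seen, were Vwf, the gene of von Willebrand factor (-0.93 ± 0.15, adjusted p = 0.00636), and the phosphatase gene Ptprb (-0.55 ± 0.12, adjusted p = 0.0309). Ptprb lost its call when any of 7 single arrays was left out, with an adjusted p of up to 0.094.

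Genes of endothelial tip cells, which lead new sprouts, rose too: 11 of 21 over all genes tested and 16 adjusted over the list alone, with 0 and 1 lower. Their median was 0.62 (camera adjusted p = 1.0e-15, and 0.0129 as an adjusted p with an estimated correlation), and 5 of 5 arrays lay above every control. In the list of VEGF-dependent endothelial genes 11 of 23 rose and 0 fell, or 15 and 0 adjusted over the list alone, with a median of 0.55 (camera adjusted p = 1.0e-14, and 0.0129 as an adjusted p with an estimated correlation) and the same 5 of 5 arrays. The tip cell and VEGF-dependent lists share 16 of their tested genes, so they are not independent of each other. With the pan-endothelial list they share 3 and 5. Aplnr and its ligand gene Apln, which act in vessel sprouting, rose by 0.97 ± 0.12 (adjusted p = 0.000517) and 0.94 ± 0.15 (0.00589). Pdgfb, which recruits pericytes, rose by 0.87 ± 0.15 (0.0071) and Mcam by 0.92 ± 0.13 (0.00156). Esm1 (-0.48 ± 0.26, adjusted p = 0.447, lower on 4 of 5 arrays), Angpt2 (0.79 ± 0.24, 0.126) and Flt1 (-0.53 ± 0.27, 0.419) did not pass the test.

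**Figure D1:**
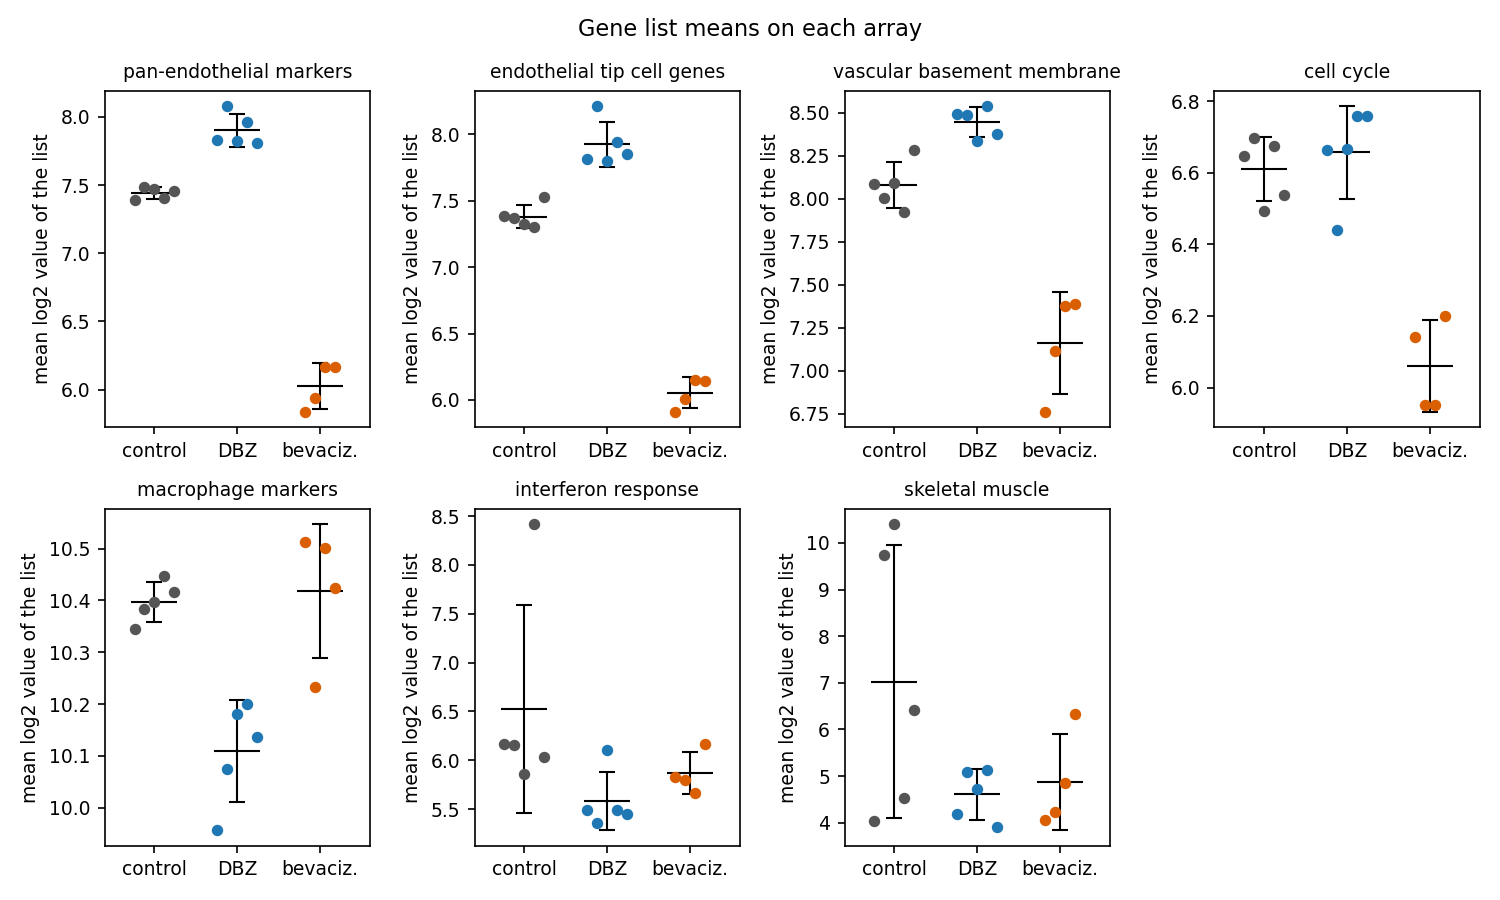
Mean log2 expression of 7 gene lists on each array. Points are arrays, and bars are group means ± SD for control (n = 5), dibenzazepine (n = 5) and bevacizumab (n = 4); the pan-endothelial means are 7.44, 7.90 and 6.03.

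Known Notch targets did not pass as a group. Of 12 measured, 1 rose and 0 fell over all genes tested, against 1 and 2 adjusted over the list alone. The median was -0.12 (camera adjusted p = 0.212, and 0.442 as an adjusted p with an estimated correlation). Their mean per array was 5.91 ± 0.11 (SD, n = 5) in controls and 5.71 ± 0.08 (SD, n = 5) with the inhibitor, while 4 of 5 treated arrays lay below every control (exact p = 0.0159, and 0.0658 after adjustment over the lists). Hes1 (1418102_at, -0.11 ± 0.08, adjusted p = 0.587), Hey2 (-0.19 ± 0.09, 0.389), Nrarp (-0.07 ± 0.14, 0.894, lower on 2 of 5 arrays) and Dll4 (-0.14 ± 0.17, 0.793, lower on 4 of 5) did not pass. Nor did Notch3 (-0.83 ± 0.26, 0.143) or the arterial connexin gene Gja4 (-1.27 ± 0.31, 0.0528). Hey1 (3.16 in controls, 3.17 with the inhibitor) and Heyl (3.22 and 3.16) lay under the expression filter and were not tested. Hes1 (4.28 to 4.48 in controls, 3.98 to 4.30 with the inhibitor) and Hey2 (4.43 to 4.77 and 4.26 to 4.47) lay near the log2 4 filter. A fall in Hes1 or Hey2 could therefore be understated. The same holds for Notch3 (3.03 to 3.47 with the inhibitor) and Gja4 (2.48 to 4.43), which lay mostly below log2 4. Gja4 and Notch3 were the 2 that were lower adjusted over the list alone. Notch4, a receptor of endothelial cells, was the 1 that rose (0.63 ± 0.13, adjusted p = 0.0205), a call lost without dibenzazepine replicate 2 (0.57, adjusted p = 0.0664). Notch receptors, ligands and gamma-secretase components held no other called gene (1 of 16, median -0.02, adjusted p = 0.394), and the sign of that median turned to 0.01 after quantile normalisation. Nrarp and the probe set used for Dll4 did not follow the rise of the pan-endothelial markers (median 0.59). The other probe set of Dll4 changed by a different amount with bevacizumab, as given below. For Dll4 the statement therefore holds for the probe set used only. Whether Notch signalling fell relative to the endothelial signal was not tested, so unchanged Notch signalling is not shown.

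Vascular basement membrane genes rose, 4 of 14 over all genes tested and 7 adjusted over the list alone (median 0.42, camera adjusted p = 1.9e-06, and adjusted p = 0.215 with an estimated correlation), with 5 of 5 arrays above every control (exact p = 0.00794). The 4 were Nid2 (0.91 ± 0.19, adjusted p = 0.0215), Col15a1 (0.87 ± 0.21, 0.0459), Col4a2 (0.55 ± 0.12, 0.0254) and Col4a1 (0.53 ± 0.12, 0.0354). Their calls were lost on leaving out 2, 9, 5 and 9 of the 10 arrays in turn, with adjusted p of up to 0.112. Nid2, Col4a2, Col4a1 and Lamb1 are also in the tip cell and VEGF-dependent lists, as is Mcam, named next. The basement membrane list is therefore not independent of those lists. Among 14 pericyte and smooth muscle markers Mcam rose and Rgs5 fell by 1.88 ± 0.33 on the log2 scale (adjusted p = 0.00904). Adjusted over the list alone 3 were higher and 5 lower, while the median was -0.35 (camera adjusted p = 0.201, and 0.044 without control replicate 2) and 5 of 5 arrays lay below every control (exact p = 0.00794). Pdgfrb, a pericyte receptor, stood at -0.77 ± 0.19 (adjusted p = 0.0515). Fibroblast and fibrillar matrix genes had a median of -0.58 (camera adjusted p = 6.3e-08, and adjusted p = 0.484 with an estimated correlation), with 3 of 5 arrays below every control (exact p = 0.0556). Over all genes tested 1 of these 23 fell, Lox, which cross-links collagen (-1.05 ± 0.25, adjusted p = 0.0446), against 5 adjusted over the list alone. Without dibenzazepine replicate 1 the adjusted p of Lox was 0.1, and 7 of the 10 single arrays ended its call. Col1a1 did not pass (-0.69 ± 0.20, adjusted p = 0.109).

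**Figure D2:**
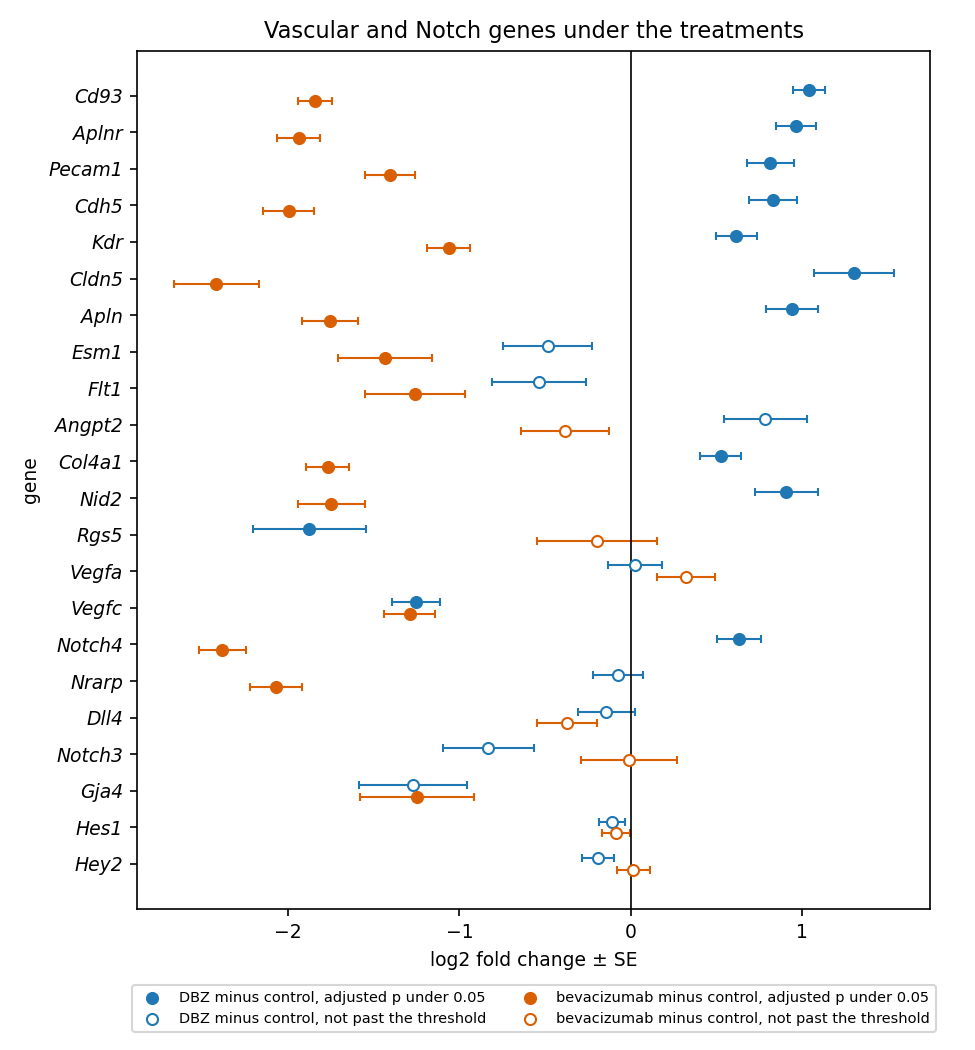
Change in 22 vascular and Notch pathway genes with each treatment against control, as log2 fold change ± SE (5 dibenzazepine, 4 bevacizumab and 5 control arrays). Filled points passed an adjusted p of 0.05; Cd93 lies at 1.04 with dibenzazepine and -1.85 with bevacizumab, and Vegfc at -1.25 and -1.29 (-0.45 and -0.28 with unique probe sets).

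Of the immune lists, 4 were called lower with dibenzazepine, and none of these calls held with an estimated correlation. The 19 macrophage markers had a median of -0.24 (camera adjusted p = 6.8e-05, and adjusted p = 0.215 with an estimated correlation), and their mean went from 10.40 ± 0.04 to 10.11 ± 0.10 (SD, n = 5 each) with 5 of 5 arrays below every control (exact p = 0.00794). None of them passed over all genes tested, against 5 lower adjusted over the list alone, and Itgam, an integrin of myeloid cells, stood at -0.51 ± 0.12 (adjusted p = 0.0504). Interferon response genes had a median of -0.89 (22 tested, camera adjusted p = 1.7e-10, and adjusted p = 0.369 with an estimated correlation), with 4 of 5 arrays below every control (exact p = 0.0238, and 0.0863 after adjustment over the lists). This median was -0.33 without control replicate 4, the tumour with high interferon genes. Of these genes 4 fell over all genes tested and 10 adjusted over the list alone. Ifit1, an antiviral effector, fell by 1.83 ± 0.41 on the log2 scale (adjusted p = 0.0339), Ifit2 by 1.47 ± 0.30 (0.0206), Ifit3 by 1.47 ± 0.33 (0.0358) and Oas1a by 0.76 ± 0.14 (0.0103). The first 3 of these calls were lost without dibenzazepine replicate 2 (adjusted p = 0.0975, 0.0663 and 0.106). MHC class II and dendritic cell genes (7 tested, 1 lower, Itgax at -0.90 ± 0.20, adjusted p = 0.0348) had a median of -0.80 (camera adjusted p = 0.0165, and adjusted p = 0.587 with an estimated correlation), with 4 of 5 arrays below every control (exact p = 0.135). Without control replicate 4 it was -0.28 (adjusted p = 0.0741), and Itgax lost its call without any of 8 single arrays (adjusted p of up to 0.0828). Inflammatory cytokines and chemokines had 0 called genes of 17, 2 lower adjusted over the list alone, and a median of -0.32 (camera adjusted p = 0.0101, and adjusted p = 0.349 with an estimated correlation), 4 of 5 arrays below every control (exact p = 0.0476, and 0.153 after adjustment over the lists). That median was -0.18 without control replicate 4 (adjusted p = 0.0271) and lost its call without control replicate 5 (-0.30, adjusted p = 0.0598).

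The largest rises after dibenzazepine were in Tmem255a, a membrane protein gene (3.98 to 6.14, a change of 2.16 ± 0.16, adjusted p = 9.5e-06, 1456596_at), and Mest, an imprinted gene (7.98 ± 0.29 to 9.99 ± 0.32, SD, n = 5 each, adjusted p = 0.000517, 1423294_at). The protocadherin gene Pcdh17 rose by 1.69 ± 0.15 (adjusted p = 3.3e-05) and Odc1, the first enzyme of polyamine synthesis, by 1.68 ± 0.19 (0.00034). The potassium channel gene Kcna5 rose by 1.44 ± 0.13 (3.6e-05), the phosphodiesterase gene Pde2a by 1.37 ± 0.15 (0.000277) and the transcription factor gene Ets2 by 1.24 ± 0.18 (0.00172). Controls lay near background for Kcna5 (2.99 to 3.09) and Pcdh17 (3.54 to 3.80), so the sizes of these rises are uncertain. Fbp1, an enzyme of glucose synthesis, rose by 1.59 ± 0.24 (0.00334) from a control level near background (3.26), and Adm, the vasodilator adrenomedullin, by 1.22 ± 0.25 (0.0242). Besides Rgs5 and the Ifit genes, the largest falls were in the acute phase gene Saa3 (-2.12 ± 0.51, 0.0497), Plac8 (-2.06 ± 0.40, 0.0143) and the lubricin gene Prg4 (-1.98 ± 0.41, 0.0242). They were followed by the interferon-inducible Ifi209 (-1.80 ± 0.38, 0.0267), Ms4a4c (-1.68 ± 0.33, 0.0181), the collagenase gene Mmp13 (-1.68 ± 0.38, 0.0354) and C1qtnf3 (-1.55 ± 0.27, 0.00717). Leaving out 1 array ended the calls of Adm, Saa3, Prg4, Ifi209, Ms4a4c and Mmp13, with an adjusted p of up to 0.122 for Saa3 without dibenzazepine replicate 4. Vegfc fell by 1.25 ± 0.14 on the log2 scale (0.00034), and by 0.45 when only probe sets unique to 1 transcript were used, with its call kept.

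Other programmes and cell types did not pass with dibenzazepine, apart from skeletal muscle genes (13 tested, 0 called, median -2.58, camera adjusted p = 1.2e-05, and adjusted p = 0.527 with an estimated correlation), with 1 of 5 arrays below every control (exact p = 0.135) and 2 of 5 controls high in muscle RNA. Without control replicate 3 that median was -1.71, and without control replicates 2 and 3 it was -0.42 (adjusted p = 0.246). The myosin gene Myh4 stood at -3.20 ± 1.22 (adjusted p = 0.239) and the creatine kinase gene Ckm at -2.96 ± 1.17 (0.257). Cell cycle genes had a median of 0.05 (0 of 27 called, adjusted p = 0.117), hypoxia response genes -0.05 (Adm up and Lox down, or 1 and 3 adjusted over the list alone, adjusted p = 0.871; 0.02 after quantile normalisation), VEGF and angiopoietin ligands and receptors 0.00 (3 up and 1 down, or 5 and 2 adjusted over the list alone, adjusted p = 0.212) and immediate early genes 0.04 (adjusted p = 0.264). In the last list Dusp1 rose by 0.58 ± 0.14 (adjusted p = 0.0462), a call lost on leaving out any of 9 single arrays (up to 0.129). Vegfa stood at 0.03 ± 0.16 (adjusted p = 0.976, higher on 4 of 5 arrays). Medians of the remaining lists were -0.36 for lymphatic endothelium, -0.08 for matrix proteases (0.02 after quantile normalisation) and 0.11 for neutrophils (-0.38 without control replicate 4). They were -1.33 for the 2 natural killer cell genes measured (-0.49 without control replicate 4), 0.02 for T and B cells (-0.03 without control replicate 5) and -0.16 for mast cells (0.04 without control replicate 3). The others were -0.03 for keratinocytes, 0.30 for adipocytes (-0.33 without control replicate 2), -0.23 for erythroid genes, 0.06 for neural and glial genes, 0.06 for the unfolded protein response and 0.18 for cholesterol synthesis. Cell cycle genes were called higher without control replicate 2 (adjusted p = 0.0434) or dibenzazepine replicate 2 (0.0033), and the unfolded protein response without control replicate 5 (0.0368) or dibenzazepine replicate 5 (0.0207). The 19 lists that did not pass had adjusted p values from 0.117 to 0.962, and in 6 of them median, mean and test differed in sign.

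In all, 191 of 8940 genes passed with dibenzazepine, 98 higher and 93 lower (143 and 82 after quantile normalisation), of which 48 changed at least 2-fold (25 higher, 23 lower). Of the 29 lists 10 passed, 4 higher and 6 lower, and the 3 endothelial lists, which share genes, alone held with an estimated correlation. Among the 47 called genes named, 19 kept their call under every alternative tried and 18 lost it when at least 1 single array was left out (adjusted p of up to 0.129). The number called was 119 without control replicate 2 and 102, 96, 127 and 125 without dibenzazepine replicates 1, 2, 4 and 5.

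Bevacizumab against control asks how the stroma differs after this antibody. Blood vessel genes fell. The pan-endothelial mean went from 7.44 ± 0.04 (SD, n = 5) to 6.03 ± 0.17 (SD, n = 4), with all 4 treated arrays below every control (exact p = 0.00794), and 33 of the 36 genes fell while 0 rose. Tie1, an endothelial receptor kinase (1416238_at), went from 6.60 ± 0.10 to 4.18 ± 0.25, Cdh5 from 7.18 ± 0.21 to 5.18 ± 0.23 and the basement membrane collagen Col4a1 (1452035_at) from 12.22 ± 0.13 to 10.46 ± 0.30. Cell cycle genes had a mean of 6.06 ± 0.13 (SD, n = 4) against 6.61 ± 0.09 (SD, n = 5), a fall called with the preset correlation but not with an estimated one (adjusted p = 0.124 with an estimated correlation).

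The pan-endothelial median was -1.37 (camera adjusted p = 4.7e-36, and adjusted p = 0.00374 with an estimated correlation), and all 36 genes were lower adjusted over the list alone. Sox7, a transcription factor of vessel development, fell by 3.09 ± 0.18 on the log2 scale (adjusted p = 2.1e-07), Icam2 by 2.52 ± 0.15 (2.9e-07), Cldn5 by 2.42 ± 0.25 (3.1e-05) and Tie1 by 2.42 ± 0.11 (7.1e-08). Cdh5 fell by 2.00 ± 0.15 (1.5e-06), Cd93 by 1.85 ± 0.10 (1.9e-07), Pecam1 by 1.41 ± 0.15 (3.3e-05), Flt1 by 1.26 ± 0.29 (0.0136) and Kdr by 1.06 ± 0.13 (0.000107). Tip cell genes fell in 16 of 21 cases (17 adjusted over the list alone) with a median of -1.55 (camera adjusted p = 4.8e-17, and adjusted p = 0.00829 with an estimated correlation). VEGF-dependent genes fell in 17 of 23 cases (18 adjusted over the list alone) with a median of -1.55 (camera adjusted p = 4.8e-17, and adjusted p = 0.00794 with an estimated correlation). In both lists 4 of 4 arrays lay below every control. Igfbp3 fell by 2.70 ± 0.27 (2.2e-05), Trp53i11 by 2.46 ± 0.24 (2.1e-05) and Flt4, the receptor of VEGF-C, by 2.19 ± 0.17 (2.3e-06). Aplnr fell by 1.94 ± 0.12 (5.8e-07), Apln by 1.76 ± 0.16 (1.3e-05), Mcam by 1.76 ± 0.14 (2.3e-06), Adm by 1.65 ± 0.27 (0.00159) and Esm1 by 1.43 ± 0.27 (0.00445). Angpt2 did not pass (-0.38 ± 0.26, adjusted p = 0.351).

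The largest falls outside these lists were in the potassium channel subunit Kcne3 (1418499_a_at, -4.25 ± 0.47, adjusted p = 5.5e-05, to 3.59, near background), Mest (7.98 ± 0.29 to 4.21 ± 0.63, adjusted p = 8.9e-07), Gpihbp1, which anchors lipoprotein lipase on capillaries (1453022_at, -3.43 ± 0.26, 1.5e-06), and Gimap4 (-2.39 ± 0.43, 0.003). The rises were smaller. The protease gene Mmp11 rose by 0.99 ± 0.24 (0.0177), the ribosomal protein gene Rpl27a by 0.84 ± 0.19 (0.0122) and the fructose kinase gene Khk by 0.82 ± 0.18 (0.00953). Rptor, a subunit of the mTOR complex, rose by 0.66 ± 0.12 (0.00363), Tmem176a by 0.65 ± 0.12 (0.00415) and Zfp444 by 0.63 ± 0.11 (0.00322). Sned1 rose by 0.92 ± 0.26 (0.0349), Fcgbp by 0.76 ± 0.21 (0.032), Hgh1 by 0.69 ± 0.18 (0.0273) and the fibronectin gene Fn1 by 0.64 ± 0.19 (0.0399). The last 4 lost their call when single arrays were left out, with adjusted p values of up to 0.0852 (Sned1, without bevacizumab replicate 3), 0.0756 (Fcgbp, without control replicate 2), and 0.0812 (Hgh1) and 0.124 (Fn1) without bevacizumab replicate 2.

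With bevacizumab 4 Notch target genes fell, beside 33 of 36 pan-endothelial markers (median -1.37). Whether Notch signalling fell beyond this loss of endothelial signal was not tested. The Notch target list had a median of -0.27 (4 of 12 lower, 0 higher, camera adjusted p = 0.035, and adjusted p = 0.124 with an estimated correlation), with 4 of 4 arrays below every control (exact p = 0.00794). Without bevacizumab replicates 3 or 4 the list did not pass (-0.15 with an adjusted p of 0.0771, and -0.37 with 0.0692), and without replicate 1 its median was -0.18. Notch4 (1449146_at) fell by 2.39 ± 0.14 (adjusted p = 2.1e-07), Nrarp, a feedback inhibitor of Notch signalling (1417985_at), by 2.07 ± 0.15 (1.5e-06), while Notch1 fell by 0.74 ± 0.18 (0.0187) and Gja4 by 1.25 ± 0.33 (0.0281, and 0.0798 without bevacizumab replicate 1). Hes1 (-0.09 ± 0.08, adjusted p = 0.505; 0.05 with each array centred on its median), Hey2 (0.02 ± 0.10, 0.934, higher on 3 of 4 arrays) and Notch3 (-0.01 ± 0.28, 0.988, lower on 2 of 4; 0.12 with each array centred on its median) did not pass. With bevacizumab too, Hes1 (4.12 to 4.31) and Hey2 (4.30 to 4.73) lay near the log2 4 filter. Notch3 (3.57 to 4.80) and Gja4 (3.21 to 3.74) lay near or below it. Dll4, the ligand of tip cells, did not pass with the probe set used (1421827_at, -0.37 ± 0.18, adjusted p = 0.188), while its other probe set (1421826_at) changed from 4.25 to 2.48 (-1.77, adjusted p over all probe sets = 2.0e-05), and the mean of both passed (-1.07). Notch receptors, ligands and gamma-secretase genes did not pass as a list (4 of 16 lower, median -0.14, adjusted p = 0.139). They included Jag2 (-1.06 ± 0.27, 0.0228) and the coactivator gene Maml1 (-0.35 ± 0.09, 0.0281), which lost their calls without bevacizumab replicate 1 (Jag2, adjusted p = 0.073) and replicate 2 (Maml1, 0.0907).

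Basement membrane genes fell with the endothelial ones, 9 of 14 lower and 1 higher, or 10 and 1 adjusted over the list alone (median -1.01, camera adjusted p = 1.0e-06, and adjusted p = 0.136 with an estimated correlation), with 4 of 4 arrays below every control. Col4a1 fell by 1.77 ± 0.13 (adjusted p = 1.0e-06), Nid2 by 1.75 ± 0.20 (6.0e-05), Col18a1 by 1.67 ± 0.15 (1.2e-05) and Col4a2 by 1.65 ± 0.12 (1.5e-06). Col4a1, Nid2 and Col4a2 are also in the tip cell and VEGF-dependent lists. The VEGF and angiopoietin list, given next, shares Kdr, Tie1, Flt1, Flt4 and Pdgfb with the endothelial lists. VEGF and angiopoietin ligands and receptors had a median of -0.38 (9 of 19 lower, 0 higher, camera adjusted p = 0.00732, and adjusted p = 0.124 with an estimated correlation), which was -0.14 without bevacizumab replicate 2, and 4 of 4 arrays lay below every control. They included Vegfc (-1.29 ± 0.15, adjusted p = 7.6e-05; -0.28 and no longer called with unique probe sets), while Vegfa stood at 0.32 ± 0.17 (0.228). Pericyte and smooth muscle markers did not pass as a list (4 of 14 lower, median -0.15, adjusted p = 0.349; 0.000178 after quantile normalisation). Their 4 called members were Mcam, Abcc9 (-1.58 ± 0.27, 0.00242; -0.54 and no longer called with unique probe sets), the channel gene Kcnj8 (-1.28 ± 0.35, 0.0325, and 0.111 without bevacizumab replicate 2) and the smooth muscle gene Smtn (-0.51 ± 0.12, 0.0176). Fibroblast genes (Fn1 up, Lox down by 1.08 ± 0.26 with an adjusted p of 0.0181, and 0.0515 without bevacizumab replicate 2) had a median of -0.19 (adjusted p = 0.752). Matrix proteases had a median of -0.24 (1 higher, 4 lower, adjusted p = 0.739), with Adamts4 at -1.60 ± 0.25 (0.00112).

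Cell cycle genes fell, 13 of 27 over all genes tested and 22 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 5.2e-08, and adjusted p = 0.124 with an estimated correlation) and 4 of 4 arrays below every control (exact p = 0.00794). Birc5, an inhibitor of cell death made in mitosis, fell by 1.30 ± 0.19 (adjusted p = 0.000674), the topoisomerase gene Top2a by 1.21 ± 0.21 (0.00276), Ube2c by 1.01 ± 0.11 (5.5e-05) and the centromere histone gene Cenpa by 0.99 ± 0.11 (5.5e-05).

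Macrophage markers had a mean of 10.42 ± 0.13 (SD, n = 4) with bevacizumab against 10.40 ± 0.04 (SD, n = 5). Their median of 0.044 was called higher relative to the other genes (camera adjusted p = 0.035, and adjusted p = 0.427 with an estimated correlation), but 0 of 19 members passed, 2 of 4 arrays lay above and 1 below every control, and without bevacizumab replicate 1 the median was -0.03 (adjusted p = 0.185). Trem2, a receptor of lipid-handling macrophages, stood at 0.43 ± 0.13 (adjusted p = 0.0502) and Itgam at 0.32 ± 0.13 (0.132). Leaving out control replicate 5 ended the list's call (adjusted p = 0.0643), and its median lay between -0.03 and 0.10 with any single array left out. Adipocyte genes, a sign of surrounding fat, were called higher (median 0.79, 0 of 8 members called, camera adjusted p = 0.0158, and adjusted p = 0.597 with an estimated correlation), with 2 of 4 arrays above every control (exact p = 0.318). That list did not pass without control replicate 2 (0.35, adjusted p = 0.0944) or bevacizumab replicates 3 (0.50, 0.0739) or 4 (0.45, 0.0737), and its median was 1.33 without bevacizumab replicate 1. Interferon response genes did not pass as a list (median -0.68, adjusted p = 0.068). The list was called lower under 8 of 17 alternatives, with adjusted p values from 0.000163 to 0.793 and medians from -0.996 to -0.194, the latter without control replicate 4 (adjusted p = 0.412). Single arrays that brought the call when left out were control replicates 2 (adjusted p = 0.0368), 3 (0.0115) and 5 (0.0244). Of its members Ifit1 (-1.66 ± 0.43, 0.025) and Rsad2 (-0.32 ± 0.09, 0.0379) passed, and without bevacizumab replicate 2 Ifit1 had an adjusted p of 0.0733. Rsad2 lost its call without any of 7 single arrays (up to 0.0862). Among inflammatory genes (median -0.17, adjusted p = 0.928; 0.01 after quantile normalisation) the monocyte chemokine gene Ccl7 fell (-0.71 ± 0.16, 0.0139), a call lost under 3 of 23 alternatives (adjusted p of up to 0.131). Ccl2 was called at -0.39 ± 0.11 (0.044) and lost the call under 16 of 23, standing at -0.18 after quantile normalisation (adjusted p = 0.44). Its adjusted p was 0.133 without bevacizumab replicate 2.

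Other lists did not pass with bevacizumab. Medians were -0.52 for lymphatic endothelium (1 lower, Flt4), -0.29 for hypoxia response (1 higher and 5 lower, or 1 and 7 adjusted over the list alone), -0.06 for immediate early genes (0.09 after quantile normalisation), -0.29 for the unfolded protein response and 0.09 for cholesterol synthesis. They were -0.29 for neutrophils, 0.21 for natural killer cells (-0.11 without control replicate 2, and larger without control replicate 4, with an adjusted p of 0.0897) and 0.19 for T and B cells. For MHC class II the median was -0.06 and ran from -0.48 to 0.48 under the alternatives, with the list called higher without control replicate 4 (adjusted p = 0.0029). The others were -0.24 for mast cells, 0.18 for keratinocytes, -0.37 for erythroid genes and 0.14 for neural and glial genes. Skeletal muscle genes stood at -2.60 (adjusted p = 0.0833), with Myh4 at -3.28 ± 1.30 (0.119) and Ckm at -2.83 ± 1.25 (0.158), beside the 2 muscle-rich controls. The muscle list was called lower without control replicates 1 (-3.29, adjusted p = 0.00627) or 4 (-3.24, 0.00385), and stood at -1.65 without control replicate 3. T and B cell genes were called higher without control replicates 1 (adjusted p = 0.0406) or 4 (0.0283) or bevacizumab replicates 3 (0.0364) or 4 (0.0329). SCID mice lack mature T and B cells, so signal in this list can be background or human RNA on mouse probes. Of its members Cd4, Cd8a and Ms4a1 lay mostly near the log2 4 filter, and Cd22 lay at 6.01 to 7.44. Lymphatic genes were called lower without control replicate 4 (0.0357), and keratinocyte genes higher without bevacizumab replicate 3 (0.0364). The neutrophil list, with an adjusted p of 0.928 on all arrays, was called lower without control replicate 4 (-0.67, adjusted p = 0.0462). The 20 lists that did not pass had adjusted p values from 0.0617 to 0.928, and median, mean and test differed in sign in 4. In an exact test of list means, adjusted over the lists, 4 of the 20 passed. Keratinocytes (above every control on 4 of 4 arrays) and Notch receptors and ligands (below on 4 of 4) had exact p = 0.0256 each. Lymphatic (below on 4 of 4) and pericyte genes (3 of 4) had exact p = 0.0418 each. Of the 3 keratinocyte genes tested 0 were called, and Krt5 was 6.82 on bevacizumab replicate 4, against 4.78 to 5.05 on the other bevacizumab arrays. Of the 4 lymphatic genes tested Flt4 alone was called.

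In all, 1045 of 8940 genes passed with bevacizumab, 115 higher and 930 lower (11% higher), and 180 changed at least 2-fold, all of them lower. This split depends on scaling: quantile normalisation, which moved the median of all genes by 0.129, gave 331 higher and 425 lower, and centring each array on its median, a move of 0.133, gave 273 and 509. Of the 56 called genes named, 30 kept their call under every alternative tried, 13 lost it without at least 1 single array (adjusted p of up to 0.139), and 649 genes were called without bevacizumab replicate 2. Of the 29 lists 9 passed, 2 higher and 7 lower, against 14 without control replicate 4, and the 3 endothelial lists, which share genes, alone held with an estimated correlation.

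Dibenzazepine against bevacizumab tests whether the treatments differed in their effects. Vessel genes differed most, with a pan-endothelial mean of 7.90 ± 0.12 (SD, n = 5) against 6.03 ± 0.17 (SD, n = 4). Mest stood at 9.99 ± 0.32 with dibenzazepine and 4.21 ± 0.63 with bevacizumab, a difference of 5.78 ± 0.26 (adjusted p = 3.9e-09), and Cldn5 at 9.03 ± 0.42 and 5.30 ± 0.43. Tmem119, a gene known from microglia (1451344_at), was lower with dibenzazepine, at 5.65 ± 0.13 against 7.17 ± 0.10.

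Of the pan-endothelial genes 32 of 36 were higher with dibenzazepine and 0 lower (median 1.94, camera adjusted p = 6.6e-41, and adjusted p = 0.00149 with an estimated correlation). The tip cell list (19 of 21, median 2.10, camera adjusted p = 7.5e-26) and the VEGF-dependent list (19 of 23, median 2.10, 8.1e-24) had an adjusted p of 0.00149 each with an estimated correlation. Cdh5 differed by 2.83 ± 0.15 (adjusted p = 1.9e-08), Apln by 2.70 ± 0.16 (6.6e-08), Pecam1 by 2.22 ± 0.15 (1.5e-07), Kdr by 1.68 ± 0.13 (5.6e-07), Angpt2 by 1.17 ± 0.26 (0.00761) and Esm1 by 0.95 ± 0.27 (0.0367, and 0.0948 without bevacizumab replicate 1). Beside Mest and Cldn5 (3.73 ± 0.25, 1.7e-07), the largest differences were in Kcne3 (5.16 ± 0.47, 3.8e-06), Gpihbp1 (4.43 ± 0.26, 4.8e-08) and Sox7 (3.99 ± 0.18, 3.9e-09). Basement membrane genes were higher with dibenzazepine (11 of 14, median 1.20, camera adjusted p = 2.9e-10, and adjusted p = 0.0684 with an estimated correlation), as were cell cycle genes (18 of 27, median 0.56, 1.0e-10, and again adjusted p = 0.0684 with an estimated correlation). VEGF and angiopoietin genes had 8 higher and 1 lower of 19 (median 0.36, camera adjusted p = 0.00523, and adjusted p = 0.108 with an estimated correlation). In each of these 6 lists 5 of 5 dibenzazepine arrays lay above every bevacizumab array. Apart from the cell cycle list they share genes, as given above, so they are not independent of each other.

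Notch targets did not pass against the other genes (3 of 12 higher, median 0.00, camera adjusted p = 0.422), yet their mean was 5.71 ± 0.08 (SD, n = 5) with dibenzazepine and 5.30 ± 0.07 (SD, n = 4) with bevacizumab. On 5 of 5 dibenzazepine arrays it lay above every bevacizumab array (exact p = 0.00794, and 0.0177 after adjustment over the lists; fry adjusted p = 3.0e-05). With a median of 0.00, the gap in means was carried by few members. Nrarp was higher with dibenzazepine by 2.00 ± 0.15 (adjusted p = 6.1e-07). Notch4 had risen by 0.63 with dibenzazepine and fallen by 2.39 with bevacizumab, each against control. Pan-endothelial markers differed by a median of 1.94 between the treatments. Whether Notch signalling differed beyond this endothelial difference was not tested. Hes1 (-0.02 ± 0.08, adjusted p = 0.908, lower on 1 of 5 arrays), Hey2 (-0.21 ± 0.10, 0.219), Dll4 (0.23 ± 0.18, 0.476), Notch3 (-0.82 ± 0.28, 0.0757), Flt1 (0.72 ± 0.29, 0.135) and Vegfa (-0.30 ± 0.17, 0.307) did not pass. For Dll4 this holds for the probe set used. Its other probe set fell with bevacizumab against control, as given above, so equal levels with the treatments are not shown. Nor are they shown for Hes1, Hey2 and Notch3, which lay near or below the log2 4 filter with each treatment. Notch receptors, ligands and gamma-secretase genes had 4 of 16 higher (median 0.23, camera adjusted p = 0.0811, and 0.0377 without bevacizumab replicate 2). Of their arrays too 5 of 5 lay above (exact p = 0.0177 after adjustment over the lists, fry adjusted p = 8.8e-05).

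Macrophage markers were lower with dibenzazepine than with bevacizumab, 7 of 19 lower and 1 higher, or 11 and 1 adjusted over the list alone (median -0.36, camera adjusted p = 1.2e-06, and adjusted p = 0.0742 with an estimated correlation), with 5 of 5 arrays below every bevacizumab array (exact p = 0.00794). Fibroblast genes had a median of -0.32 (1 lower, camera adjusted p = 0.00107, and adjusted p = 0.588 with an estimated correlation) with 1 of 5 arrays below. MHC class II genes had -0.70 (1 lower, camera adjusted p = 0.00428, and adjusted p = 0.495 with an estimated correlation) with 4 of 5. Interferon genes had -0.20 (0 called, camera adjusted p = 0.0101, and adjusted p = 0.66 with an estimated correlation) with 4 of 5. The fibroblast median was -0.15 without dibenzazepine replicate 2, and -0.49, -0.17 and -0.16 without bevacizumab replicates 1, 3 and 4. The interferon list did not pass without bevacizumab replicate 4 (-0.13, adjusted p = 0.059), and its median was -0.31 without dibenzazepine replicate 3. Besides Tmem119 (-1.52 ± 0.11, 3.1e-07) the largest falls were in Mmp13 (-2.29 ± 0.40, 0.00151), Rgs5 (-1.68 ± 0.35, 0.00531), Ppfia4 (-1.45 ± 0.18, 8.6e-05) and AI504432 (-1.52 ± 0.43, 0.031), the last not called without bevacizumab replicate 1 (0.0896).

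In all, 1117 genes differed between the treatments, 940 higher and 177 lower with dibenzazepine (84.2% higher), and 286 by at least 2-fold (263 higher, 23 lower). After quantile normalisation the split was 682 higher and 363 lower, and with arrays centred on their medians, which moved the median of all genes by -0.111, it was 671 and 360. The 19 lists that did not pass had medians from -1.54 to 0.39 and adjusted p values from 0.0607 to 0.866, and in 3 of them median, mean and test differed in sign. Beside the 2 Notch lists, 5 of these had all 5 dibenzazepine arrays outside the range of the bevacizumab arrays. These were the hypoxia response (6 of 26 higher and 1 lower), immediate early (3 of 18 higher) and lymphatic lists (1 of 4 higher) above it. The keratinocyte list (0 of 3 called) lay below it (exact p = 0.0177 for each of these lists after adjustment over the lists). The unfolded protein response lay above it (4 of 17 higher, exact p = 0.0329). Camera gave the lymphatic and keratinocyte lists adjusted p values of 0.506 and 0.132. The lymphatic median was 0.04, and its called gene, Flt4, is also in the tip cell list. Krt5 was 6.82 on bevacizumab replicate 4, against 4.78 to 5.05 on the other bevacizumab arrays. With fry the hypoxia list did not pass (adjusted p = 0.129). With camera the unfolded protein list passed without dibenzazepine replicate 5 (adjusted p = 0.0117), and adipocyte genes were called lower without dibenzazepine replicate 1 (0.0138) or bevacizumab replicate 1 (0.0103).

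The last comparison asks which genes moved with both treatments. Of 1136 genes called with either, 100 were called with both. The most common pattern was opposite: 74 genes rose with dibenzazepine and fell with bevacizumab, against 10.2 for independent lists. They include Mest, Cldn5, Adm, Notch4, Kdr, Pecam1, Cdh5, Mcam, Aplnr, Apln, Cd93, Nid2, Col4a1 and Col4a2. Another 25 fell with both (9.67 for independent lists), among them Vegfc, Lox and Ifit1. With unique probe sets Vegfc was not called with bevacizumab (-0.28), and the calls of Lox and Ifit1 were lost with either treatment when single arrays were left out (adjusted p of up to 0.1 and 0.0975). A single gene rose with both, Fgf13, which was chosen after its values were seen (0.53 ± 0.09, adjusted p = 0.0093, and 0.33 ± 0.10, 0.0446, the latter not called without any of 7 single arrays, with adjusted p values of up to 0.139). None fell with dibenzazepine and rose with bevacizumab (1.20 for independent lists).

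**Figure D3:**
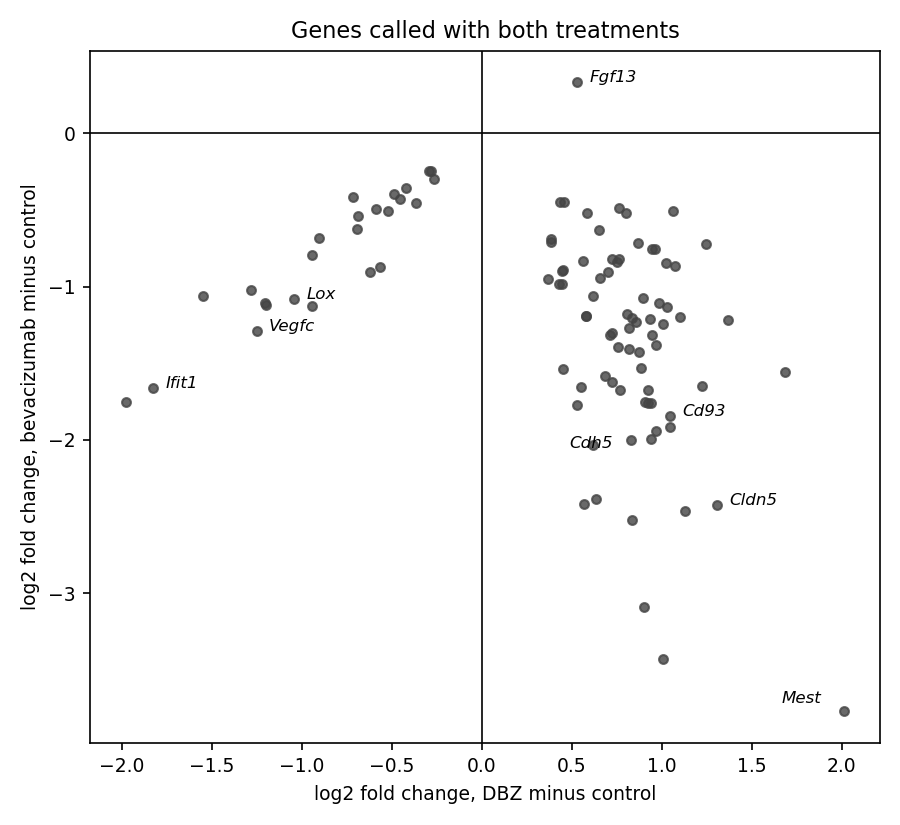
Log2 fold change with dibenzazepine (x axis) and with bevacizumab (y axis), each against the 5 controls, for the 100 genes called with both. There are 74 genes to the right and below the zero lines, 25 below both and 1 above both.

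Because the controls are shared, some overlap in the same direction can arise without a shared effect. Simulated unchanged groups gave on average 0.1 genes lower with both and 0 in each other pattern. With all group effects removed, few genes can be called at all. These simulated counts therefore do not show how much of the overlap comes from the shared controls. Across the 8940 genes, which are not independent replicates, the fold changes correlated at 0.165, while the simulated groups gave 0.452 on average, with 87 of 100 draws as high as the observed value. With the controls split between the comparisons the mean correlation was -0.0353. The opposite pattern then held 34.3 genes on average (13 to 49), and 3.35 genes were called in the same direction. Each split left 2 or 3 controls per comparison, so fewer genes could be called, and the opposite pattern shrank too. The lower count in the same direction therefore does not show how much of the overlap comes from the shared controls. The 26 genes called in the same direction became 10, 11, 11, 13, 10 and 15 without control replicate 2, dibenzazepine replicates 1, 2, 4 and 5, and bevacizumab replicate 3, and the 74 opposite ones became 47 without dibenzazepine replicate 2.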

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

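For the 3 patterns weighed below, all tests of an explanation were chosen only after the result was seen, and only the counts of other splits of the arrays were planned. In 405 groups of values, 1 per gene list or named gene and treatment group, the highest or lowest array was tested by Dixon's ratio. Chance gives about 1 in 20, or 20.25, and 42 stood far from the rest of their group.

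Control replicate 4 held 10 of these. Its mean was high for natural killer cell markers (9.15), MHC class II and dendritic cell genes (10.9), interferon response genes (8.42), Gimap4 (10.81), Ifi209 (7.61) and Usp18 (6.68), and low for erythroid genes (3.66), Abcc9 (6.55), Kcne3 (5.78) and P2ry12 (6.22). Among the other controls, Hes1 was high on replicate 2 (4.48) and immediate early genes on replicate 5 (7.31).

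With dibenzazepine, replicate 1 was low for Nrarp (6.19) and high for Sned1 (5.14). Replicate 2 was high for Fbp1 (5.91) and low for Fcgbp (5.51), Rgs5 (6.55) and Tmem119 (5.42). Replicate 3 was high for interferon response genes (6.10), Ms4a4c (6.83) and Oas1a (7.08), and low for Hes1 (3.98), Khk (4.26) and Ppfia4 (4.62). Replicate 4 was low for neutrophil markers (7.66) and Vegfa (5.66) and high for Adamts4 (7.09) and Zfp444 (5.35). Replicate 5 was set apart by VEGF and angiopoietin genes (6.59) and was high for Flt1 (6.03).

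With bevacizumab, replicate 1 was low for Notch targets (5.19), immediate early genes (6.77) and Abcc9 (5.04). Replicate 2 was high for neural and glial genes (5.38) and low for Angpt2 (4.53) and Tmem119 (7.03). Replicate 3 was low for Hes1 (4.12) and high for Tmem255a (3.92). Replicate 4 was high for Ckm (5.31), Col18a1 (6.23) and Ifit1 (4.39) and low for Saa3 (8.05).

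Among 1583 probe sets with no gene name or several, which the comparisons of genes leave out, 24 passed with dibenzazepine against control (14 higher, 10 lower), 135 with bevacizumab against control (26 higher, 109 lower) and 89 between the treatments (75 higher, 14 lower).

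The fall of the 36 pan-endothelial markers with bevacizumab was weighed first. A lower share of mouse RNA in these tumours would lower all mouse cell types alike, but the macrophage median was 0.044, its lowest member was -0.51, 0 of 19 members were as low as the endothelial median, and the gap between the lists differed from controls (exact p = 0.00794). After quantile normalisation of the deposited values the fall remained, with a median of -1.23 (exact p = 0.00794). The raw arrays were not processed anew, so the authors' own normalisation cannot be excluded by this. Fewer endothelial cells with unchanged expression could account for it if the members fell by about the same amount: the spread between members was 0.615 against 0.515 from probe sets of the same gene and the standard error, and 0.0513 of 10000 simulated lists were as spread. This lies at the threshold, and its reading was settled only after the value was seen, so fewer endothelial cells and lower expression per cell cannot be told apart.

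The rise of the same markers with dibenzazepine was weighed second. Dilution by skeletal muscle RNA in control replicates 2 and 3 does not account for it, since the median without them was 0.60 (exact p = 0.0179). More endothelial cells with unchanged expression would raise all members by about the same amount, if only these cells made the markers and the mix of vessels stayed the same. The spread between members was 0.490 against 0.229, and Vwf and Ptprb fell. The share of simulated lists as spread was 1e-04, the smallest that 10000 simulations can give. An equal rise of all members therefore does not account for the pattern. Markers shared with other cells and a changed mix of vessels were not modelled, so a change in cell number is not excluded. A change of expression within endothelial cells under the inhibitor, with or without a change in their number, remains a hypothesis and was not tested further.

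The lower interferon response genes with dibenzazepine were weighed last. A single control tumour with high interferon genes, replicate 4, accounts for much of the size, since the median was -0.33 without it against -0.89 with it. It does not account for all of it: 5 members were called lower without that array, Ifit1 (-1.40, adjusted p = 0.0149), Ifit2 (-1.15, 0.00735), Ifit3 (-1.19, 0.0499), Oas1a (-0.64, 0.00842) and Usp18 (-0.67, 0.0352, against -0.90 and 0.0515 with all arrays). The list had an exact p of 0.0318 without that array, before adjustment. With all arrays its exact p did not pass after adjustment over the lists (0.0863). Usp18 was chosen after its values were seen. With bevacizumab the list had a median of -0.19 without that array (adjusted p = 0.412), and over 17 alternatives its adjusted p ran from 0.000163 to 0.793. No biological explanation was tested.

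Chance can be excluded for the number of genes called in each comparison, since of 100 splits of the arrays drawn from 126, the real one alone gave as many. The highest other split gave 1 gene against 191 for dibenzazepine, 378 against 1045 for bevacizumab and 355 against 1117 between the treatments. It cannot be excluded for the number of lists called: 31, 34 and 17 of the 100 splits gave as many as the real 10, 9 and 10, and the highest others gave 18, 19 and 12.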

How the results depend on the processing

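Leaving out controls 2 and 3 or bevacizumab arrays 1 and 2, and list tests with centred arrays, were tests chosen after the data were seen. No named gene changed direction past the threshold. Of the named genes that were called, 19 of 47, 30 of 56 and 19 of 22 (dibenzazepine, bevacizumab, between treatments) kept their call under all alternatives run, as did 3 of 10, 3 of 9 and 3 of 10 called lists. Genes near background (below log2 4 in a group) have understated changes on arrays. The causes of the changes below were not tested, except where fewer arrays or genes were used.

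Genes called with dibenzazepine (191) became 122 with no filter, 388 with array weights, 100 with the muscle covariate, 77 without controls 2 and 3, 48 at 2-fold, 354 at an adjusted p of 0.10 and 96 to 195 without single arrays. Those with bevacizumab (1045) became 658 with unique probe sets, 509 with only the 2 groups fitted, 562 with the muscle covariate, 543 without controls 2 and 3, 404 without bevacizumab arrays 1 and 2, 180 at 2-fold, 1603 at an adjusted p of 0.10 and 649 to 1248 without single arrays. Those between treatments (1117) became 649 without bevacizumab arrays 1 and 2, 286 at 2-fold and 841 to 1195 without single arrays. Lists called (10, 9 and 10) became 3, 3 and 3 with an estimated correlation, 5, 11 and 13 with fry, and 6, 11 and 14 with the exact test of list means. They became 17 with no filter for bevacizumab, and without single arrays 9 to 12 and 8 to 14 for the first 2 comparisons. Without control replicate 4 the neutrophil list of the second was called lower (-0.67), against the direction of its test with all arrays. Without single arrays its median ran from -0.67 to 0.12.

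Genes called in the same direction with both treatments (26) became 15 with no filter, 15 after quantile normalisation, 3.35 with controls split, 5 without controls 2 and 3, 17 without bevacizumab arrays 1 and 2, and 10 to 35 without single arrays. Opposite ones (74) became 46 with no filter, 35.15 with controls split, 29 without controls 2 and 3, and 47 to 85 without single arrays. With the controls split, the correlation (0.165) was -0.0353 and the covariance (0.0168) was -0.00491. Replicate numbers did not pair the arrays (13 pairs, r from -0.483 to 0.496, 5 above 0.1); with them as a block 156, 914 and 1054 genes and 10, 9 and 11 lists were called.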

Other observations

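The tests of these genes were chosen only after their values were seen. Of 6 genes known from microglia and related macrophages, picked for their values and not tested as a group, 4 were lower with dibenzazepine than in controls. In the fixed macrophage list 0 of 19 members passed that comparison. The tumours grew under the skin, and which of their cells made these transcripts was not tested. Olfml3 (1448475_at) fell from 8.21 ± 0.21 to 6.89 ± 0.09 (SD, n = 5 each; -1.32 ± 0.09, SE, adjusted p = 9.5e-06) and Tmem119 from 6.88 ± 0.22 to 5.65 ± 0.13 (-1.24 ± 0.10, 2.9e-05), on 5 of 5 arrays each. Slamf9 fell by 0.75 ± 0.11 (0.00368) and P2ry13, a nucleotide receptor, by 0.50 ± 0.09 (0.0126, a call lost under 4 of 23 alternatives, up to 0.0723). P2ry12 (-0.70 ± 0.21, 0.113, but called at -0.90 with 0.00869 without control replicate 4) and the fractalkine receptor gene Cx3cr1 (-0.43 ± 0.12, 0.0896) did not pass, although Cx3cr1 was called under 3 of 23 alternatives (0.0317 with array weights, 0.0348 without control replicate 5).

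With bevacizumab none of the 6 passed against control: Tmem119 stood at 0.29 (adjusted p = 0.107), Olfml3 at 0.04 (0.835, higher on 3 of 4 arrays), Slamf9 at 0.27 (0.162), P2ry12 at 0.40 (0.254, 3 of 4), P2ry13 at 0.16 (0.302) and Cx3cr1 at 0.20 (0.327, 3 of 4). After quantile normalisation Tmem119 (0.48, adjusted p = 0.011) and Slamf9 (0.48, 0.026) were called higher. The direct test between the treatments called all 6 lower with dibenzazepine, on 5 of 5 arrays each: Tmem119 (-1.52 ± 0.11, 3.1e-07), Olfml3 (-1.36 ± 0.10, 3.5e-07), P2ry12 (-1.10 ± 0.22, 0.0042), Slamf9 (-1.02 ± 0.12, 5.2e-05), P2ry13 (-0.66 ± 0.10, 0.000439) and Cx3cr1 (-0.63 ± 0.13, 0.00454). The call of Cx3cr1 was lost without bevacizumab arrays 1 and 2 (-0.49, adjusted p = 0.0935).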
